A study of Mus musculus with 10 samples.

How the data were processed

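Total RNA from BMEL cells, a bipotential mouse embryonic liver line, was measured on 10 single-colour Affymetrix mouse arrays after transfection with Oligofectamine. Per the labels, 5 arrays came from cells given a locked nucleic acid oligonucleotide antisense to miR-30a and 5 from cells given a scrambled oligonucleotide, and the RNA was amplified and biotin-labelled with the MessageAmp Premier kit. The group and the replicate number of each array were taken from its title. The labels do not say whether the 5 replicates of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

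The deposited values are log2 expression values, 1 per probe set and array. Their scale was read from the values, whose highest was 14.1827, above the 11.09 that a natural log of the scanner's ceiling would allow. The summary method, background correction and normalization the authors used are not given in the sources used here. Array medians lay between 5.21 and 5.24, so the deposited log2 values were used as they stand. The table holds 45101 probe sets, of which 64 are array controls. The platform annotation gave 1 gene symbol for 34945 probe sets and several for 932, and 9160 are not listed in it. Of the probe sets with 1 symbol, 34754 matched a current gene by its identifier. Probe sets with several symbols were not used, which left the control gene Gapdh out of the test. For each of 18193 genes the probe set with the highest mean over the 10 arrays was kept, and genes whose mean lay under 4.559, the level below which 40% of probe sets fall, were left out. That gave 12633 tested genes. The number of arrays limits the precision.

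The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Changes are antisense minus scrambled on the log2 scale, with the standard error of the fit. Gene lists were tested with camera at a preset correlation of 0.01 where at least 5 members were measured, which held for 19 of 20 lists, and again with an estimated correlation and with fry, with Benjamini-Hochberg adjustment over the lists. List means per array were compared with two-sided exact permutation tests that ignore the replicate numbers. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

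The lists, the tests and the rule for named genes were fixed before the data were examined. The lists were hepatocyte markers, biliary epithelial markers, liver transcription factors and hepatoblast genes, reported miR-30 targets, TGF-beta, activin and BMP signalling, Notch signalling, epithelial junction and keratin genes, mesenchymal and EMT genes, interferon response, cell cycle, p53 targets, microRNA machinery, autophagy, cholesterol synthesis and SREBP2 targets, unfolded protein and integrated stress response, glycolysis and hypoxia genes, ribosomal protein genes, and markers of mesenchymal and stellate, endothelial, and blood and macrophage cells. The rule named the 15 largest increases and the 15 largest decreases among genes past the threshold whose 5 antisense arrays all lay on one side of the scrambled mean. It also named the 4 members of each list with the smallest p, or 8 of the reported miR-30 targets, and Nfyc, Alb, Afp, Krt19, Sox9, Hnf4a, Snai1, Tnrc6a, Actb and Gapdh. Clone names were counted and not named, which passed over 2 increases and 6 decreases.

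Both groups carry the replicate numbers 1 to 5. Over the 12633 genes, the deviations of same-numbered arrays from their group means correlated at 0.172, 0.377, 0.112, 0.152 and 0.335, against a mean of -0.0594 and a range of -0.312 to 0.231 for arrays of different number. Deviations from a group mean cancel out within the group, so the negative mean follows in part from the same-numbered values. The values 0.172, 0.112 and 0.152 also lie inside the range for arrays of different number. The numbers were treated as pairing the samples, but the pairing was not tested. This pairing comes from the values, since the labels do not say what a number marks. The comparison fixed beforehand has no block, and a fit with the replicate block is given beside it where it changes a call or moves a count by over 1.5 times, counts adjusted over a list included.

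The procedure was tested on simulated data. With 200 of 12633 genes changed in 10 runs of the antisense against scrambled comparison, it recovered 58.1% of changes of 0.25, 95.8% of changes of 0.5 and 99.9% of changes of 1 on the log2 scale, with 4.51% of calls false. Of simulated lists without a change, 1.89% had a camera p under 0.05. The simulated genes varied independently, so this share does not hold for lists whose members vary together. In the real data the estimated correlation was 0.535 for the glycolysis and hypoxia genes.

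The alternatives were a replicate block, quantile normalization, centring each array on its median, no filter or a 60% filter on dim probe sets, the mean of a gene's probe sets, every probe set on its own, an intensity trend with robust estimation, array weights, and each array left out in turn. After the data had been seen, fits without the 2 arrays at the ends of the first principal component, with the 3′ over 5′ signal ratio as a covariate, and with the mean of the glycolysis and hypoxia genes as a covariate were added. After the gene values had been seen, 5 further lists were written. They were further p53 targets, ERK pathway output genes, squamous epithelial genes, gastric and intestinal epithelial genes, and cleavage-stage embryo genes. Some genes that prompted them were not called, such as Usp17la (limma adjusted p = 0.102, and 0.0866 with the replicate block). A planned comparison of genes with and without miR-30 seed sites was not run, because no 3′ UTR sequences were used here. Mature miR-30a was not analysed here, so the extent of its knockdown is not shown.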

Results

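Gene expression was measured in BMEL cells, a cell line from mouse embryonic liver that can take on features of hepatocytes or of bile duct cells. The cells had been transfected with a locked nucleic acid oligonucleotide antisense to miR-30a (5 arrays) or with a scrambled control oligonucleotide (5 arrays). The comparison asks which transcripts differ in level when miR-30a is targeted, in cells that can enter either liver epithelial lineage. All 10 arrays had nearly equal medians, from 5.21 to 5.24 on the log2 scale, and 12633 genes were tested.

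Ak1, an adenylate kinase that interconverts adenine nucleotides, had the largest increase, from 6.36 ± 0.11 (SD, n = 5) in scrambled arrays to 7.37 ± 0.066 (SD, n = 5) in antisense arrays. That is a 2.01-fold difference (log2 change 1.01, SE 0.054, limma adjusted p = 1.63e-06). The RNA-binding protein gene Celf5 rose by 0.81 (SE 0.080, adjusted p = 0.000497), the cytokine gene Csf2 by 0.65 (SE 0.070, adjusted p = 0.000804) and the membrane transporter gene Slc4a11 by 0.64 (SE 0.047, adjusted p = 3.73e-05). Tcstv1, a transcript of the cleavage-stage embryo, had the largest measured decrease and fell by 1.48 (SE 0.26, adjusted p = 0.0143), a 2.78-fold difference, though the adjusted p was 0.0521 without antisense replicate 4. Gkn2, which encodes a secreted gastric protein, fell by 0.81 (SE 0.14, adjusted p = 0.0124).

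In all, 193 genes passed the threshold, 146 higher and 47 lower with the antisense oligonucleotide, and the median size of their log2 change was 0.295. Only 5 of them differed by at least 2-fold: Ak1, Tcstv1 and, chosen after their values were seen, AF067061, Gm20767 and D13Ertd608e, which fell by 1.13, 1.10 and 1.01. Without scrambled replicate 5 all 5 still passed the test, but the changes of AF067061, Gm20767 and D13Ertd608e were -0.885, -0.867 and -0.768, which left 2 genes of at least 2-fold. With 1 array left out that count ranged from 1 to 5. The antisense means of Tcstv1 (4.31) and D13Ertd608e (4.49) lay under the filter level of 4.559, so the size and rank of these decreases are uncertain. The values of the groups did not overlap for 185 of the 193. Over all genes tested this held for 3.92%, against 0.794% by chance. With the replicate block 385 genes passed, 253 higher and 132 lower, and 184 were shared with the unblocked fit. The count fell to 95, 92 and 123 without antisense replicate 3, 4 or 5 and to 101 without scrambled replicate 3.

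**Figure D1:**
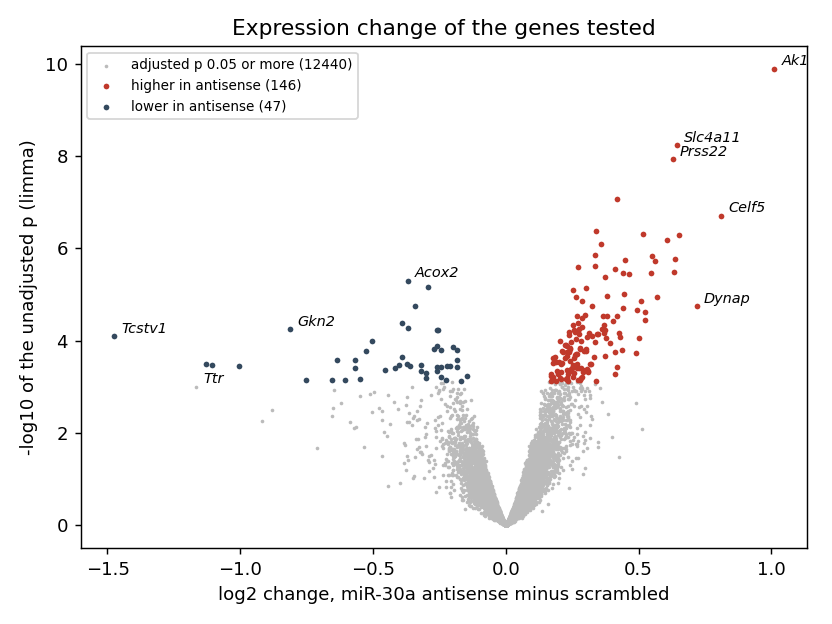
Log2 change (x axis, antisense minus scrambled) against -log10 of the unadjusted limma p (y axis) for the 12633 genes tested, 1 point per gene. Genes past an adjusted p of 0.05 are coloured, 146 higher and 47 lower, and Ak1 has the smallest p.

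Among the other genes named for a large increase were Dynap (0.72), Dcxr (0.64), which encodes a xylulose reductase, and Cpt1c (0.63), a carnitine palmitoyltransferase gene. The serine protease gene Prss22 also rose by 0.63 (adjusted p = 4.98e-05), and Btbd11 by 0.57. The small heat shock protein gene Cryab rose by 0.56, Zfp365 by 0.55, Flacc1 by 0.52, the autophagy gene Atg9b by 0.52, and Sprr2h and Serpinb5, both expressed in squamous epithelia, by 0.52 and 0.51. The other named decreases were Cst9 (-0.75), Orly (-0.66), Sfi1 (-0.64), the imprinted zinc finger gene Plagl1 (-0.57), Mansc1 (-0.53, with an antisense mean of 4.40, also under the filter level) and Car6 (-0.50), which encodes a secreted carbonic anhydrase. Further decreases were the trefoil factor gene Tff3 (-0.46), the pyruvate dehydrogenase kinase gene Pdk4 (-0.42), the Wnt antagonist gene Sfrp1 (-0.40), Cyp2c68 (-0.39), the histone gene H3c11 (-0.39), Wnk3 (-0.37) and the peroxisomal oxidase gene Acox2 (-0.37). These decreases had adjusted p-values from 0.00265 (Acox2) to 0.0488 (Orly). Of the 15 named decreases, 12 missed the threshold with at least 1 array left out, with adjusted p up to 0.138, while Gkn2, H3c11 and Acox2 passed each time. The calls of Sfrp1, Plagl1, Flacc1 and Atg9b rest on 1 probe set each, since a second probe set above the filter had a log2 change of 0.08, -0.09, 0.04 and 0.08.

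**Figure D2:**
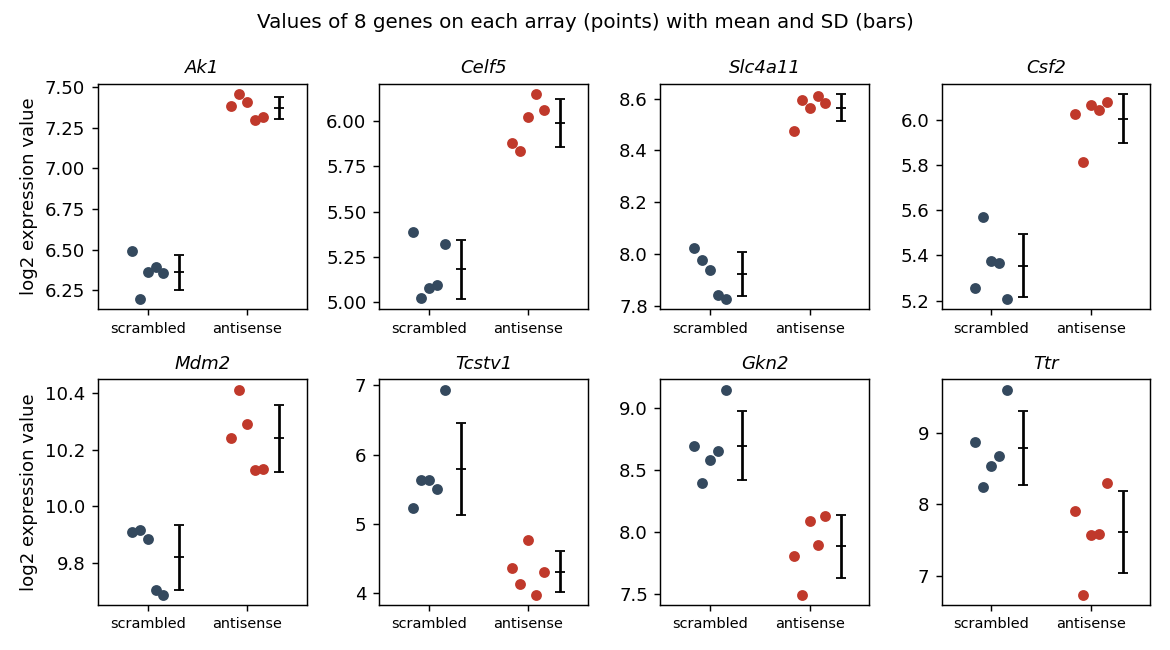
Log2 expression value (y axis) of 8 genes on each of the 5 scrambled and 5 antisense arrays (points), with the group mean and SD (bars). The antisense arrays of Ak1 all lie above the scrambled arrays, and scrambled replicate 5 has the highest Tcstv1 value, 6.94.

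The p53 targets, genes induced by the stress-responsive transcription factor p53, moved up together. Of 20 measured members 7 rose and none fell, and adjusted over the list alone 17 rose and none fell. Ddit4l rose by 0.44 (SE 0.067, adjusted p = 0.00669), Mdm2, the ubiquitin ligase that restrains p53, by 0.42 (SE 0.066, adjusted p = 0.0085), the cyclin gene Ccng1 by 0.29 (SE 0.046, adjusted p = 0.00887) and the DNA polymerase gene Polk by 0.27 (SE 0.045, adjusted p = 0.0108). The other called members, named after their values were seen, were Trp53inp1 (0.34), the nucleotide excision repair gene Ercc5 (0.24) and the cell cycle inhibitor gene Cdkn1a (0.19). The mean change of the list was 0.21, with 19 of 20 members above 0 and Gadd45a at -0.07. Camera gave an adjusted p of 1.5e-16, and the adjusted p was 0.000636 with an estimated correlation. The list mean was higher in the antisense array of all 5 pairs. An exact permutation test without pairing gave p = 0.00794, its smallest possible value, and 0.0754 after adjustment over the 19 lists. Only the p53 targets and the reported miR-30 targets reached that smallest value. The adjusted p could therefore be no lower for either, and this test does not rank these lists. An exact test within 5 pairs could give no p under 0.0625. With the replicate block 11 members rose, and with the block the adjusted p was 0.0347 with an estimated correlation.

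**Figure D3:**
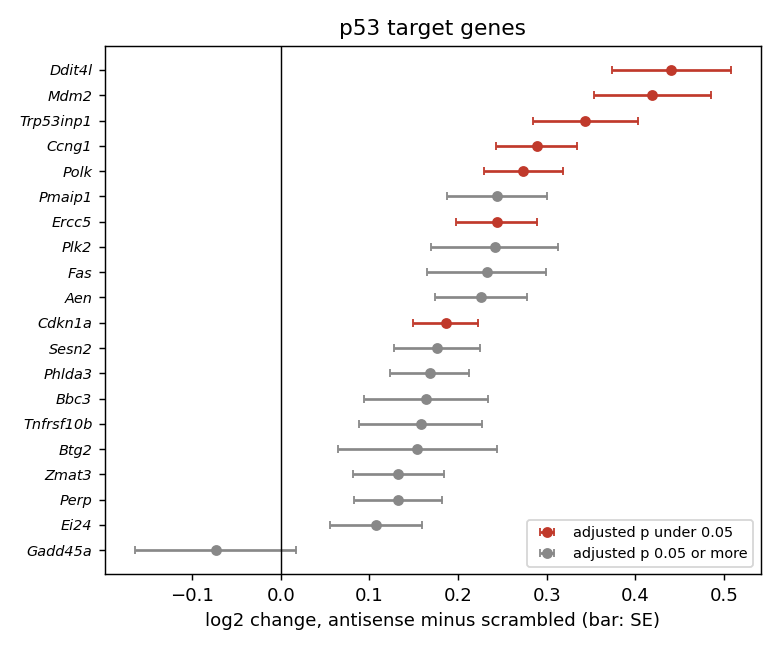
Log2 change (x axis, antisense minus scrambled) of the 20 measured p53 targets, with bars for the SE and n = 5 arrays per group. The 7 members past an adjusted p of 0.05 are in red, and Gadd45a is the 1 member below 0.

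The reported miR-30 targets, genes that earlier work has linked to direct repression by this microRNA family, shifted up by a small amount. Their mean log2 change was 0.07, with 19 of 22 measured members above 0. None passed the test over all genes and 1 of them, Tnrc6a, rose adjusted over the list alone, or 3 with the replicate block (Tnrc6a, Itgb3 and Socs1). Tnrc6a, a component of the silencing complex, had a change of 0.18 (SE 0.046, adjusted p = 0.0812 over all genes) and Snai1, a driver of epithelial-mesenchymal transition, of 0.25 (SE 0.092, adjusted p = 0.252). Itgb3, an integrin subunit gene, had a change of 0.23 (adjusted p = 0.169) and rose with the replicate block (adjusted p = 0.0359). A second Itgb3 probe set above the filter had a change of -0.04, so the rise of Itgb3 rests on 1 probe set. The changes of Socs1 (0.24), Ccn2 (0.14), Smad1 (0.10), Becn1 (0.08) and Galnt7 (0.06) did not pass the test over all genes. Other probe sets above the filter were at 0.19 and -0.03 for Smad1 and at -0.04, 0.02 and 0.06 for Becn1. Camera called the list at an adjusted p of 0.0429, which was lost with an estimated correlation (adjusted p = 0.197). The list mean was higher in the antisense array of all 5 pairs. Without pairing the exact permutation p was 0.00794, the smallest possible, and 0.0754 after adjustment. Within 5 pairs an exact test could give no p under 0.0625. The call is borderline: with 1 array left out the adjusted p ranged from 0.0113 to 0.106 and passed the threshold in 3 of 10 fits. It was 0.106, 0.0573, 0.0673 and 0.0532 without antisense replicates 1 to 4, and 0.0517, 0.101 and 0.0507 without scrambled replicates 1, 4 and 5.

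No list of liver epithelial lineage genes was called with all arrays and without the replicate block, though the means of the hepatocyte markers and of the liver transcription factors were lower in the antisense array of all 5 pairs (exact permutation p = 0.0238 and 0.214 without pairing, and 0.113 and 0.407 after adjustment). None of the 8 measured hepatocyte markers passed the test over all genes, while adjusted over the list alone 1 rose and 2 fell (mean -0.15, median -0.02, camera adjusted p = 0.372). Ttr, the thyroid hormone carrier transthyretin, was at 8.79 ± 0.51 (SD, n = 5) in scrambled and 7.62 ± 0.57 (SD, n = 5) in antisense arrays. Its change of -1.17 (SE 0.27) had a limma adjusted p of 0.0574 without and 0.000812 with the replicate block. Apoa1 (-0.21) and Apob (0.15), both apolipoprotein genes, Afp (0.10) and Alb (-0.03) did not pass. Of 13 biliary epithelial markers none passed, while adjusted over the list alone 3 rose and 1 fell, or 2 with the replicate block, where the water channel gene Aqp1 (-0.14) also passed (camera adjusted p = 0.762). Sox9, a duct and progenitor transcription factor, had a change of 0.17 (adjusted p = 0.0662), Itgb4 of 0.16, Slc4a2 of 0.14 and Krt19 of -0.01. The RNA-binding protein gene Bicc1 had a change of -0.17 and fell with the replicate block (adjusted p = 0.043). The 16 liver transcription factors and hepatoblast genes had 13 members below 0 and none past the threshold, also when adjusted over the list alone. With the replicate block Cebpa, a hepatocyte transcription factor gene, fell adjusted over the list alone (adjusted p = 0.0443). Cebpa was at -0.25, Onecut1 at -0.11, Igf2 at -0.09, Foxa1 at -0.09 and Hnf4a at -0.02. Camera gave this list an adjusted p of 0.0623, which became 0.0302 with the replicate block, 0.0113 without antisense replicate 5, and 0.0296 and 0.0278 without scrambled replicates 2 and 4. The list was thus near the threshold, and with the block the adjusted p was 0.295 with an estimated correlation. For the same list fry gave an adjusted p of 0.456 without and 0.00225 with the block.

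Cholesterol synthesis genes and glycolysis and hypoxia genes were called lower as lists, without a single member past the threshold over all genes. Adjusted over the list alone none passed either, but with the replicate block 3 glycolysis and hypoxia genes did: Ndrg1, Ankrd37 and Pfkp. Of 18 cholesterol genes 15 were below 0 (mean -0.07), among them Insig1 (-0.17), Dhcr7 (-0.14), Mvd (-0.13) and Hmgcs1 (-0.11). Camera gave an adjusted p of 0.00181, and the adjusted p was 0.587 with an estimated correlation. Of 17 glycolysis and hypoxia genes 15 were below 0 (mean -0.10), among them Ankrd37 (-0.35), Ndrg1 (-0.29), Bnip3 (-0.26) and Pfkp (-0.18). Camera gave an adjusted p of 0.00412, and the adjusted p was 0.633 with an estimated correlation. Per array, the means of both lists overlapped between the groups (exact permutation p = 0.0952 and 0.27), and both were lower in the antisense array of 4 of 5 pairs. Without antisense replicate 2 both lists missed the threshold (adjusted p = 0.0726 each), and without scrambled replicate 1 the glycolysis and hypoxia genes did (adjusted p = 0.0792).

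**Figure D4:**
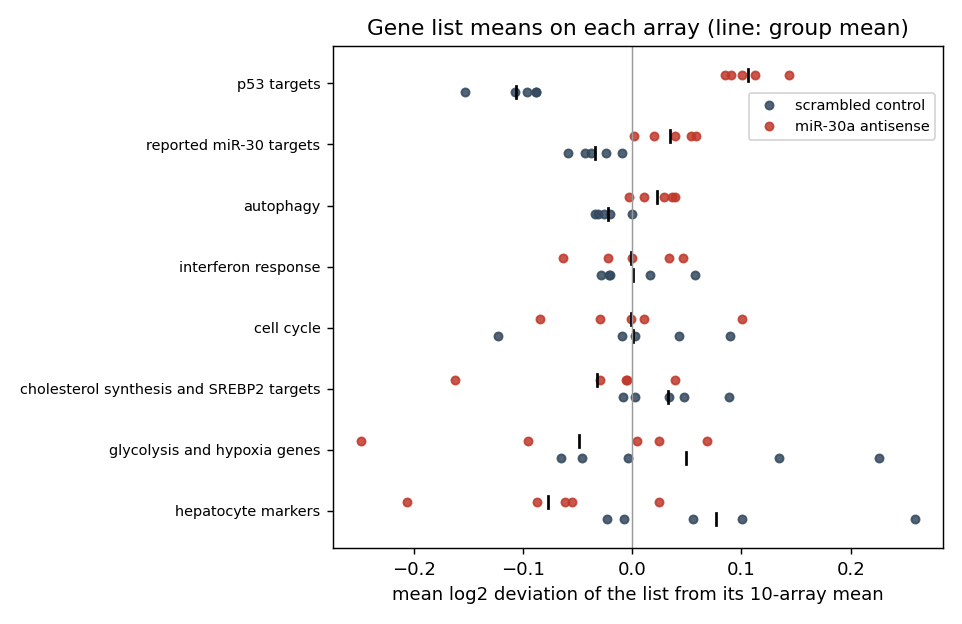
Mean log2 deviation of 8 gene lists from their mean over the 10 arrays (x axis), 1 point per array, with a line at each group mean. The p53 targets separate the groups, at 0.106 ± 0.0234 (SD, n = 5) in antisense and -0.106 ± 0.0273 (SD, n = 5) in scrambled arrays, while the glycolysis and hypoxia genes overlap.

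Of the signalling lists, 1 of 30 TGF-beta, activin and BMP genes rose: Inhba, an activin subunit gene, by 0.45 (SE 0.063, adjusted p = 0.00441, and 0.0944 with the mean of its probe sets). Adjusted over the list alone, Inhba rose and 3 members fell, and with the replicate block Bmp4 (0.15) and Acvr1 (0.19) rose too. The BMP-responsive genes Id3 (-0.24, adjusted p = 0.0506) and Id1 (-0.19, adjusted p = 0.0768) fell with the replicate block (adjusted p = 0.0134 and 0.0439), and the activin receptor gene Acvr2a was at -0.15. This list was not called (camera adjusted p = 0.762), and its mean of 0.01 and its median of -0.01 differ in sign, with camera's direction down. None of the 17 Notch genes passed, over all genes or adjusted over the list alone (camera adjusted p = 0.762), with Nrarp at 0.11, Rbpj at 0.07, Maml1 at -0.05 and Dll1 at -0.15.

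No member passed the test over all genes in 8 further lists of cell state. Adjusted over the list alone, 1 member of the microRNA machinery, Tnrc6a, rose, and Sesn2 rose and Ddit3 fell in the unfolded protein and integrated stress response, and none passed in the other 6. With the replicate block Fn1, of the mesenchymal and EMT genes, also rose (adjusted p = 0.0355 over the list alone). The 16 epithelial junction and keratin genes (camera adjusted p = 0.45) included the tight junction gene Ocln at -0.19, Jup at 0.08, Cgn at -0.06 and Cldn4 at 0.05. The 11 mesenchymal and EMT genes (adjusted p = 0.101) included fibronectin, Fn1, at 0.17, Mmp14 at 0.11 and Zeb2 at -0.16. A second Zeb2 probe set above the filter was at 0.28, so the sign for Zeb2 depends on the probe set. The 22 autophagy genes (adjusted p = 0.103) had 18 members above 0, with Wipi1 at 0.17, Wipi2 at 0.13, Atg12 at 0.13 and Sqstm1 at -0.11. The 15 interferon response genes (adjusted p = 0.762) included Xaf1 at 0.17, Cxcl10 at -0.15, Eif2ak2 at 0.11 and Irf9 at 0.09. Other Eif2ak2 probe sets above the filter were at -0.08 and 0.14, so its sign depends on the probe set. The 26 cell cycle genes (adjusted p = 0.51) included Mki67 at -0.14, Mcm6 at -0.08, Mcm2 at 0.08 and Ccnd1 at 0.05. The 16 microRNA machinery genes (adjusted p = 0.762) included Ago3 at 0.13, Xpo5 at 0.11 and Dgcr8 at 0.11. Other probe sets above the filter were at -0.07 and -0.045 for Dgcr8 and 0.01 for Xpo5. For Ago3 they were at 0.02, -0.003 and 0.11, so these values depend on the probe set. The 21 unfolded protein and integrated stress response genes (adjusted p = 0.186) included Sesn2 at 0.18, Ddit3 at -0.16, Herpud1 at -0.11 and Sel1l at -0.08. The 18 ribosomal protein genes (adjusted p = 0.45) included Rps6 at -0.04, Rpl11 at -0.03, Rpl27 at -0.02 and Rps20 at -0.02. Nfyc, the host gene of other miR-30 family members, was at -0.07 (adjusted p = 0.45) and the actin gene Actb at -0.02.

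Markers of other cell types gave 1 call. Of 6 blood and macrophage markers Cd68, a lysosomal glycoprotein gene, rose by 0.39 (SE 0.072, adjusted p = 0.0176), also adjusted over the list alone, while Cx3cr1 (0.07), Csf1r (0.05) and Fcgr1 (-0.06) did not pass (camera adjusted p = 0.465). The call of Cd68 was lost without antisense replicate 3 or 4 (adjusted p = 0.0523 and 0.0551). None of 6 mesenchymal and stellate markers passed, over all genes or adjusted over the list alone (camera adjusted p = 0.762), with Acta2 at 0.06, Col1a2 at -0.08, Dcn at -0.02 and Des at 0.01. The endothelial markers had 3 measured members, too few for the list test, and Flt1 (-0.10), Erg (0.04) and Kdr (-0.02) did not pass. The 3′ over 5′ signal ratio of 4 control transcripts, a sign of RNA quality, differed by 0.02 between the groups (exact permutation p = 0.54).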

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

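The tests of RNA quality, of culture state, of a second antisense sequence, of scrambled replicate 5 and of a shared gene family were chosen after the results they bear on had been seen. Of 100 drawn splits of the 10 arrays into 5 and 5, the real one included, 1 gave as many genes as the real 193. The highest of the others gave 1 gene. This argues against chance for the count if the arrays are independent and unpaired, which the labels do not settle. Of the drawn splits, 9, the real one included, part all 5 pairs, and with the replicate block the highest other count among them was 0 against 385. So few splits cannot give a share under 0.05. For the number of called gene lists chance cannot be excluded: 17 of the 100 splits called as many as the real 4, and the highest other split called 6. Among the 9 splits that part all pairs, too few for a share under 0.05, the highest other called 3. The mean of the p53 targets was as large in 1 of the 100 splits, the real one, at 0.213 against 0.144 in the highest other. The p53 list means of the groups do not overlap, so no other split could be as large. This repeats the exact permutation test and adds no further support.

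In 16 of 270 groups of 5 values 1 array stood apart from the other 4, where chance gives 13.5, and 8 of the 16 were in antisense replicate 2. That array was low for Csf2 (5.815, others 6.029 to 6.082), Prss22 (6.603, others 6.731 to 6.764), Itgb3 (6.004, others 6.224 to 6.312), Insig1 (9.487, others 9.726 to 9.742), Rps20 (13.08, others 13.17 to 13.18) and Flt1 (7.945, others 8.193 to 8.274). It was high for Ccn2 (10.93, others 10.6 to 10.66) and Irf9 (6.193, others 6.073 to 6.1). Antisense replicate 3 was high for Ddit4l (7.391, others 7.223 to 7.266), and antisense replicate 4 was low for Foxa1 (7.646, others 7.74 to 7.777). Scrambled replicate 1 was low for Inhba (7.466, others 7.726 to 7.796) and high for Mvd (9.299, others 9.185 to 9.214) and Fcgr1 (4.974, others 4.845 to 4.882). Scrambled replicate 5 was low for Cpt1c (5.217, others 5.624 to 5.711) and high for Cyp2c68 (7.693, others 7.238 to 7.361) and Tcstv1 (6.94, others 5.232 to 5.642). Outside the gene measurements, the 18 hybridization spike-in probe sets differed by -0.102 between antisense and scrambled arrays (exact permutation p = 0.0238, and 0.143 after adjustment over 6 quality measures). The labels name no hybridization or array batches. A batch that runs along the groups therefore cannot be told apart from the treatment, which limits the small list shifts most.

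The p53 targets were higher in antisense arrays by a mean of 0.213. The mean was 0.208 with the 3′ over 5′ ratio as a covariate and 0.222 with the glycolysis and hypoxia mean as a covariate. Neither measure separated the groups (exact permutation p = 0.54 and 0.27), so these fits could hardly have moved the mean. They argue only against a difference in RNA quality or culture state that these measures track. Other differences in RNA quality or culture state were not tested. Whether the shift follows from the loss of miR-30a or from another effect of this oligonucleotide cannot be told apart, because the design holds 1 antisense sequence. The mean change of the reported miR-30 targets themselves was 0.069, with none of 22 past the test over all genes and a camera call that was lost with an estimated correlation (adjusted p = 0.197).

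Of 9 cleavage-stage embryo genes measured above the filter, 5 fell in antisense arrays, or 4 with the replicate block. The mean of the 9 was -0.766, but 7 of them had prompted the list, so this mean is no test of the group. Scrambled replicate 5 had the highest Tcstv1 value, but the mean of the 9 was still -0.585 without that array, which argues against it as the whole cause. The members that had not prompted the list cannot tell signal shared within a repeated gene family apart from a change of each gene. Only Duxf3 and Sp110 had not prompted it, and neither passed (mean -0.09). Usp17la (-0.882, adjusted p = 0.102) and Zfp352 (-0.564, adjusted p = 0.166), by name from different families, were lower without overlap between the groups. Both had been picked for their values and neither passed, so they do not settle the question. No biological explanation was tested.

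Camera called the cholesterol synthesis genes and the glycolysis and hypoxia genes lower, without a member past the test over all genes, and both calls were lost with an estimated correlation (adjusted p = 0.587 and 0.633). A culture state that varied from array to array is the explanation weighed for both. The list means were lower in the antisense array of 4 of 5 pairs each, with mean differences of -0.0652 and -0.0981 and SDs of 0.0666 and 0.109 for the differences within pairs. The exact sign-flip p was 0.125 for both, where 5 pairs can give no less than 0.0625. With so few pairs, such variation and an effect of the antisense oligonucleotide cannot be told apart.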

How the results depend on the processing

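The fits without the 2 arrays at the ends of the first principal component, with the 3′ over 5′ ratio and with the glycolysis and hypoxia mean as covariates were chosen after seeing the data. All 36 called named genes had the same sign in every alternative fit that gave the gene a value, which were 20 or 21 fits per gene. Of the 36, 22 passed the threshold in each of these fits. The count of 193 changed genes became 385 with the replicate block (253 higher, 132 lower), 344 with array weights (271 higher, 73 lower), 303 with an intensity trend and robust estimation (233 higher) and 128 without the 2 principal component arrays (24 lower). With 1 array left out it ranged from 92 to 201, with 78 to 160 higher and 14 to 41 lower. The genes lower were 27 with every probe set on its own and 31 with the glycolysis and hypoxia covariate. The 4 called lists became 1 with an estimated correlation and 1 to 6 with 1 array left out (1 without antisense replicate 2, 2 without scrambled replicate 1). The p53 targets passed under all 23 alternatives, with adjusted p from 4.58e-19 to 0.000636, and with the replicate block at 0.00107 with fry and 0.0347 with an estimated correlation. For the cholesterol genes the adjusted p was 0.587 with an estimated correlation, 0.415 with fry, 0.167 with the glycolysis and hypoxia covariate, 0.134 without the principal component arrays and 0.000112 to 0.0726 with 1 array left out. For the glycolysis and hypoxia genes it was 0.633 with an estimated correlation, 0.465 with fry, 0.181 with array weights, 0.796 with their own mean as a covariate, which removes the list by construction, 0.315 without the principal component arrays and 0.000245 to 0.0792 with 1 array left out. For the reported miR-30 targets it was 0.197 with an estimated correlation, 0.105 with the 60% filter, 0.0829 without the principal component arrays, 0.0762 with the mean of probe sets, 0.062 without a filter, 0.0594 with the 3′ over 5′ covariate, 0.0551 with array weights and 0.0113 to 0.106 with 1 array left out. It was 0.0128 with fry and 0.0302 with the replicate block, and the list passed under 9 of 23 alternatives in all. The cause of these changes was not tested. Fits with arrays left out also hold fewer arrays, and the effect of that was not tested either. Other probe sets of called genes had the opposite sign, for Sfrp1 at 0.0781 above the filter and, below the filter where the sign says little, for Cryab (-0.0286), Inhba (-0.0117), Orly (0.05496), Plagl1 (0.0188) and Sfrp1 (0.104), while brighter probe sets of Cryab (0.48) and Orly (-0.45) had the sign of the call. Beyond the calls given beside the results, the replicate block changed no camera call of a list and no call of a named gene over all genes tested. Among the lists not called, 17 of 340 alternative values, over 5 lists, passed the threshold: autophagy, cell cycle, liver transcription factors and hepatoblast genes, mesenchymal and EMT genes, and the unfolded protein and integrated stress response. Fry also called 4 lists, but not the same 4. It called autophagy (adjusted p = 0.0169) and the mesenchymal and EMT genes (adjusted p = 0.0364) and neither the cholesterol nor the glycolysis and hypoxia genes. With the replicate block fry called neither autophagy (adjusted p = 0.071) nor the mesenchymal and EMT genes (adjusted p = 0.102). Pseudocounts were not run, since the values are already logs, and neither was the planned comparison of miR-30 seed sites. Signal near the filter level limits the dim genes, and the number of arrays limits all.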

Other observations

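The tests of further p53 targets and of ERK, squamous, and gastric and intestinal genes use lists written after the gene values had been seen. The genes that prompted a list are left out of its test. The test of the interferon genes was also chosen after their values had been seen. Dusp5, a phosphatase gene induced by ERK signalling, rose by 0.29 (SE 0.048) and Etv4, an ETS transcription factor gene induced by it, by 0.37 (SE 0.064). Egfr, a growth factor receptor upstream of ERK, rose by 0.41 (SE 0.052, limma adjusted p = 0.00199), as did the chromatin protein gene Hmga2 by 0.34 (SE 0.036, adjusted p = 0.000804), both chosen after their values were seen. The other 14 measured ERK output genes were all above 0 (mean 0.0811), among them Egr1 (0.24) and Fosl1 (0.23), with none past the threshold and 2 with the replicate block. Camera gave p = 0.00613 for them, 0.00817 after adjustment over 4 such lists, and p = 0.0454 with an estimated correlation, 0.0908 after adjustment. Higher ERK output may accompany the antisense treatment, as a hypothesis that rests on small changes.

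Several genes of squamous epithelia rose, among them Plet1 (0.46), Serpinb5 (0.51), Sprr2h (0.52) and Bnc1 (0.41). The 11 squamous genes that did not prompt the list had a mean change of 0.0507 and a camera p of 0.209, so a shift of the class was neither shown nor excluded. Gkn2, Tff3 and Klf4 fell by 0.81, 0.46 and 0.32, and the 17 gastric and intestinal genes that did not prompt the list had a mean of -0.102, with 13 below 0. With the replicate block 9 of the 25 measured members of this list fell, against 3 without it, and 1 of the 17 against none. Camera gave p = 0.000362, 0.00145 after adjustment, but p = 0.167 with an estimated correlation. A lower level of gastric and intestinal genes as a class is a hypothesis that the test with an estimated correlation does not bear out.

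A second list of 21 measured p53 targets that shares no gene with the first was tested for a wider p53 response. It had a mean of 0.0713, with 15 members above 0 and none past the threshold, or 3 with the replicate block, and Pidd1 (0.21), Gtse1 (0.20) and Eda2r (0.26) had the smallest p. Camera gave p = 0.00312, 0.00624 after adjustment, and p = 0.0454 with an estimated correlation, 0.0908 after adjustment. A p53 response wider than the first list is consistent with these values, though weaker than in that list. A difference in interferon response between the oligonucleotides as large as the p53 shift is argued against. The upper 95% bound of the mean change of the interferon genes was 0.057. Both groups received an oligonucleotide, so a response shared by them would not show in this comparison.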
